A study of Danio rerio with 3 samples.

How the data were processed

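RNA was measured by sequencing in cells sorted from transgenic zebrafish embryos at 72 hours after fertilization. Per the labels' protocols, embryos were homogenized and filtered, between 10000 and 300000 cells were sorted per population, and total RNA was extracted with a carrier. Per the same protocols, ribosomal RNA was removed, and libraries were made with a low-input kit from 50 ng of total RNA each and sequenced on an Illumina instrument. Per the submitters' processing notes, cutadapt, TopHat2 2.0.11 and Cufflinks 2.2.1 were used, with the Zv9 (danRer7) build of the zebrafish genome. The annotation, the filters, the treatment of reads that map to several places and the number of sequenced fragments are not given in the sources used here.

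The series holds 3 libraries, 1 per group: kdrl:GFP positive cells, kdrl:GFP negative cells and cells positive for both kdrl:mCherry and sele:GFP. For the double positive cells the authors deposited 1 value per gene symbol, named as FPKM from cuffdiff in the name of the deposited sheet. FPKM divides the fragments assigned to a gene by its length and by the number of fragments of the library, so the values rank genes within a library after a length correction. Short features and a few very abundant RNAs can distort such values: 306 of 313 microRNA genes were listed at 0, and rn7sk alone took 9.95% of the summed FPKM. The smallest value above 0 was 1.5043e-05 FPKM, and 20 genes lay above 0 and under 0.01 FPKM. The values are therefore estimates that divide fragments between transcripts rather than counts, and fragment numbers were not recovered from them. Single values of near-identical gene copies are uncertain for the same reason.

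The table of the kdrl:GFP cells has 2 columns of per-sample values that were not used. Their names are numbered codes, both libraries cite the same workbook, and no label says which code stands for the positive and which for the negative cells. Neither the order of the columns nor the level of marker genes was used to assign them. The comparison of kdrl:GFP positive with negative cells, and those of double positive with kdrl:GFP positive cells, were planned as descriptions of size without a test and were not made. The planned processing alternatives for them (pseudocount, filter on low values, scaling) were not run.

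Gene lists were fixed before the data were examined: 26 lists with 689 entries for endothelial subtypes, transcription factors, signalling, blood lineages, other embryonic tissues, cell division, stress and housekeeping. Symbols were matched exactly, with 1 older symbol as a second choice where one had been noted, and 589 entries were found. No coordinates are printed, because the gene table at hand describes assembly GRCz12tu and not the build of the data. That table was used only to look up synonyms. Of the 14581 symbols, 11801 are current symbols there and 2372 more match 1 current gene as a synonym. No symbol occurred more than once.

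Each gene was given its rank percentile in the library, with ties at their mean rank. For each list the numbers of members at or above 1, 10 and 100 FPKM, the median FPKM and the median rank percentile were computed. With an even number of members, each median is the mean of the middle values. The median FPKM then need not lie exactly at the median rank percentile. A 95% order-statistic interval describes the spread of the median over the members of a list. It is not an error between samples, since genes are not replicates and there was 1 library per group. Each list's median FPKM was placed among those of 10000 random lists of the same size drawn from all genes of the table. A match on expression was planned for differences between libraries and cannot apply to levels, so these lists were not matched. This placing describes the library and gives no p-value. The procedure was tested on simulated data. Simulated lists of 20 genes were drawn from the 14581 of this library, and each was placed among fewer random lists than the fixed lists were. Of 200 unchanged lists, 5% lay above the 95th percentile of random lists. Of 10 lists whose members were multiplied 8-fold, 80% did, and such multiplication raises only members with a positive value. The unchanged lists came from the same genes as the random lists, so their share follows from the draw. It does not measure how often a list of chosen, well-studied genes is placed high. Other list sizes were not simulated. The interval was tested on 200 further lists of 20 genes, drawn separately from the same library, and held the true median in 97% of them.

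The genes named were chosen by a rule written before the data were examined. It took kdrl and sele, the 20 genes of highest FPKM outside ribosomal and mitochondrial genes, and the 4 members of highest FPKM in each list. Of the genes this rule takes, 1 is not reported here. Further members named beside them, and selp, psmd7 and mcm2, were chosen after their values were seen. Ranking within genes of at least 1 FPKM was set as an alternative before the data were examined. It was run, as were alternatives chosen after seeing the data: ranks among genes above 0, lists and random lists both limited to genes above 0 or to genes of at least 1 FPKM, ranks among genes with descriptive symbols (not provisional, microRNA or receptor family symbols), members matched through current synonyms, and lists without members shared with another list. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.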

Results

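The series profiled RNA from cells sorted from zebrafish embryos at 72 hours after fertilization. It holds 3 libraries, 1 for each sorted population. The population analysed here came from embryos that carried a red reporter driven by kdrl, a Vegf receptor gene of endothelium, and a green reporter driven by sele, the gene of the leukocyte adhesion molecule E-selectin. Cells positive for both reporters were collected, a sort aimed at endothelial cells in which the sele reporter was active. The purity of the sorted cells was not examined here, so transcripts from other cells in the library cannot be told apart. The other 2 libraries hold kdrl:GFP positive and kdrl:GFP negative cells. They were not analysed here, because the 2 value columns of their table carry names that the labels tie to neither population. The comparisons of double positive cells with either population were therefore not made, and the results below compare genes and gene groups within 1 library. There were no replicates, so no test between samples was run, no value has an error between samples, and high or low refers to other genes of the same library.

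The double positive library listed FPKM values for 14581 gene symbols. Of these, 10681 (73.3%) stood at 1 FPKM or more, 5827 at 10 FPKM or more and 803 (5.51%) at 100 FPKM or more. The median over all genes was 5.98 FPKM. A value of exactly 0 was listed for 1851 symbols (12.7%), among them 306 of the 313 microRNA genes. A listed 0 was not read as absence, because genes that dividing or living cells use also had it. The proteasome subunit gene psmd7 was listed at 0 while the other constitutive proteasome subunits in the table lay at 3.46 FPKM or above, with a median over the 38 subunits of 59.3 FPKM. The replication licensing gene mcm2 was listed at 0 while the other Mcm genes of its complex lay between 19.1 and 71.0 FPKM. The number of sequenced fragments is not given in the sources used here, so the depth is unknown and no counting interval can be attached to these values.

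Both genes whose regulatory regions drove the reporters were abundant in the double positive cells. The kdrl gene stood at 428 FPKM, rank 167 of the library, and sele at 415 FPKM, rank 178. The ratio of the values was 1.03. Another selectin gene, selp, which encodes P-selectin, stood at 4.63 FPKM, so that sele was 89.8-fold higher than selp. These values are not a measure of the transgenes. Whether the reporters carried transcribed kdrl or sele sequence was not examined, so a part of the values from such sequence cannot be separated.

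Genes known as markers of endothelium as a whole were among the most abundant transcripts of the library. All 30 of the 46 genes in this list that were found in the table exceeded 1 FPKM, 29 exceeded 10 FPKM and 21 exceeded 100 FPKM. Among these 30 genes the highest were cdh5, the gene of the endothelial cadherin, at 843 FPKM, and cldn5b, a tight junction claudin, at 653 FPKM. They were followed by ramp2, a calcitonin receptor-like accessory protein gene, at 423 FPKM and the Ets factor gene fli1a at 383 FPKM. The Vegf receptor genes kdr and flt1 stood at 199.9 and 157 FPKM, and the angiopoietin receptor gene tek at 89.1 FPKM. The lowest member was vwf, the gene of von Willebrand factor, at 8.46 FPKM. Other genes of the list, among them tie1, pecam1 and sox18, matched no symbol of the table and were not analysed here. Some members were matched only through current synonyms and are not counted in this paragraph. They were vsg1 (now plvapb) at 835 FPKM, myct1 at 477 FPKM and plvapa, under a provisional symbol, at 48.1 FPKM. The median of the list was 168 FPKM, which lay at the 96.8th rank percentile of the library (95% interval of the median over members 94.6 to 97.9). All of 10000 random lists of the same size had a lower median.

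Markers of venous, lymphatic and scavenging endothelium reached levels close to those of the general endothelial markers. All 13 members in the table exceeded 10 FPKM and 8 exceeded 100 FPKM. The scavenger receptor genes stab1 and stab2 stood at 453 and 188 FPKM. The endocytic adaptor gene dab2 stood at 444 FPKM, the orphan receptor gene gpr182 at 417 FPKM and the lymphatic and venous Vegf receptor gene flt4 at 280.4 FPKM. The venous factor gene nr2f2 stood at 114 FPKM, the lymphatic factor gene prox1a at 98.2 FPKM and ifi30, a lysosomal thiol reductase gene, at 25.2 FPKM. The list's median was 128 FPKM, at the 95.7th rank percentile (95% interval 82.8 to 98.8), above that of each of the 10000 random lists. Some of the measured members, gpr182, ifi30, tll1 and il13ra2, were put in this list with knowledge of the research group's work on niche endothelium, so they are not independent evidence. Other members (mrc1a, lyve1a, lyve1b and adra1d) matched no symbol of the table and were not analysed here.

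Arterial genes were also present at high levels, with a wider range. Of 16 members in the table, 14 exceeded 10 FPKM and 8 exceeded 100 FPKM. The aquaporin genes aqp1a.1 and aqp8a.1 stood at 908 and 568 FPKM, ranks 69 and 120. The Notch ligand genes dlc and dll4 stood at 197 and 167 FPKM, the Notch receptor gene notch1b at 186 FPKM and the arterial ephrin gene efnb2a at 183 FPKM. The Notch target gene hey2 stood at 12.1 FPKM, the SoxF gene sox17 at 5.81 FPKM and the elastic fibre gene fbln5 at 1.83 FPKM. The median was 110.4 FPKM, at the 94.9th rank percentile (95% interval 63.9 to 97.1), again above all 10000 random lists. The median of the venous, lymphatic and scavenger list was 1.16 times this median, and the intervals of the 2 lists overlapped. The closeness of these medians depended on which members were counted. Without members that are also in other lists, the 8 remaining arterial genes had a median of 23.5 FPKM, at the 77.1st rank percentile and above 95.6% of random lists, and the 7 remaining venous, lymphatic and scavenger genes had a median of 135 FPKM. With the members matched through synonyms, the arterial median was that of the connexin gene cx39.4, 34.7 FPKM, and the venous, lymphatic and scavenger list gained no member.

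**Figure D1:**
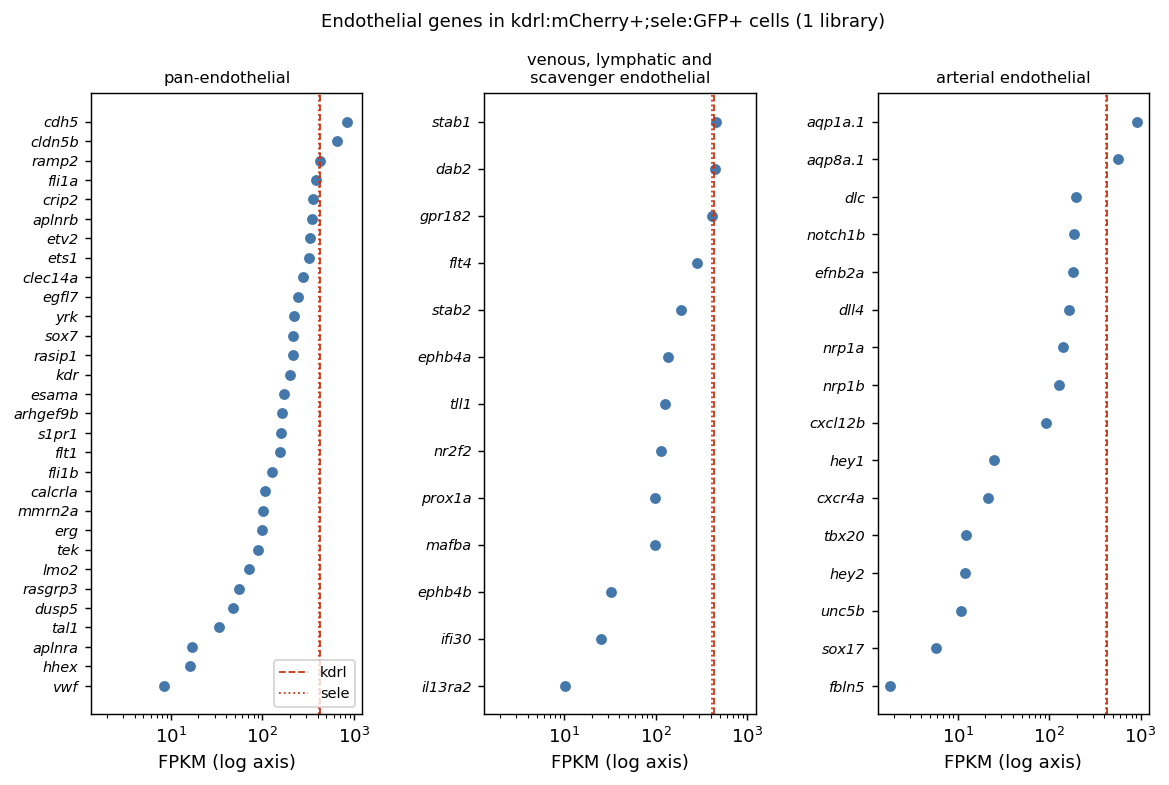
FPKM (log axis) of each gene of the pan-endothelial list, the venous, lymphatic and scavenger endothelial list and the arterial endothelial list in the 1 library of double positive cells; each point is 1 gene, and the dashed and dotted lines mark kdrl (428 FPKM) and sele (415 FPKM). The genes cdh5, cldn5b, aqp1a.1, aqp8a.1, stab1 and dab2 lie to the right of both lines, and fbln5 at 1.83 FPKM is the lowest.

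The series title concerns transcription factors. Those of the Ets, SoxF and nuclear receptor families were present throughout their list. All 27 members in the table exceeded 1 FPKM, 23 exceeded 10 FPKM and 7 exceeded 100 FPKM. Apart from fli1a, the highest were the Ets genes etv2 at 333 FPKM and ets1 at 320.1 FPKM and the SoxF gene sox7 at 217 FPKM. Further Ets genes were elk3 at 129 FPKM, fli1b at 128 FPKM and erg at 99.99 FPKM. Among nuclear receptors, nr2f2 was followed by nr2f1a at 79.2 FPKM and the retinoid X receptor gene rxraa at 47.1 FPKM, and nr2f1b was the lowest at 1.41 FPKM. The median was 39.2 FPKM, at the 85.5th rank percentile (95% interval 72.8 to 94.5), above all 10000 random lists. In the list of other endothelial factors, 22 of 24 members exceeded 10 FPKM. The Klf factor genes klf2b, klf6a and klf2a stood at 534, 432 and 173 FPKM, and klf6a is also in the list of immediate early and stress genes. The genes id3 and id1, which are known targets of Bmp signalling, stood at 436 and 429.9 FPKM. The hematopoietic and endothelial gene gata2a stood at 54.7 FPKM and its paralog gata2b at 1.27 FPKM. This list's median of 55.3 FPKM lay at the 89.5th rank percentile (95% interval 82.4 to 94.4), above all 10000 random lists.

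Components of Vegf, angiopoietin, apelin and Notch signalling had a median of 89.1 FPKM, at the 93.8th rank percentile (95% interval 64.6 to 96.7). Of 31 members in the table, 25 exceeded 10 FPKM. The apelin receptor gene aplnrb stood at 351 FPKM, its ligand gene apln at 189.9 FPKM and the neuropilin genes nrp2b, nrp1a and nrp1b at 164, 144 and 129 FPKM. Ligand genes of the Vegf family were lower, with vegfc at 15.9 FPKM, vegfaa at 11.5 FPKM and vegfab at 5.71 FPKM. The list lay above all 10000 random lists. Its 14 members that are in no other list had a median at the 67.1st rank percentile, above 91.6% of random lists.

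Secreted factors and adhesion molecules known to act on blood cells formed a mixed group. Of 29 members in the table, 12 exceeded 10 FPKM, 3 exceeded 100 FPKM and 2, csf1b and il34, were listed at 0. The highest were the growth factor gene igf2b at 269 FPKM and the Notch ligand genes dll4 and jag2b at 167 and 110.2 FPKM. The chemokine genes cxcl12a and cxcl12b, whose mammalian relative retains blood stem cells in the marrow, stood at 97.8 and 91.6 FPKM. Of the stem cell factor genes, kitlga stood at 76.3 FPKM and kitlgb at 4.35 FPKM. The cytokine genes csf3, thpo and il6 stood at 2.07, 1.06 and 0.375 FPKM. The list's median of 4.87 FPKM lay at the 46.3rd rank percentile (95% interval 34.6 to 75.7), above 34.6% of random lists and 16.4% of random lists of genes with descriptive symbols. With members and random lists both limited to genes above 0 it lay above 15.5%, and with genes of at least 1 FPKM above 39.5%.

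Lysosomal and endocytic genes were abundant. Of 35 members in the table, 29 exceeded 10 FPKM and 10 exceeded 100 FPKM. The cathepsin gene ctsla stood at 745 FPKM, the tetraspanin gene cd63 at 704 FPKM, the lysosomal membrane gene lamp2 at 367 FPKM and the lysosomal protease gene lgmn at 317 FPKM. The clathrin heavy chain gene cltca stood at 158 FPKM and its paralog cltcb at 19.2 FPKM. The median was 47.3 FPKM, at the 87.8th rank percentile (95% interval 82.3 to 93.2), above all 10000 random lists. The cell cycle and housekeeping lists, with medians of 54.3 and 81.3 FPKM, also lay above all of these. The placing therefore does not set lysosomal and endocytic genes apart from other widely used genes.

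The lists of blood cell genes had lower medians than the 3 endothelial lists. Differences between blood lineages were not tested, and most of their intervals overlapped. Of 18 stem and progenitor genes in the table, 9 exceeded 10 FPKM and none exceeded 100 FPKM. The chemokine receptor gene cxcr4b stood at 79.5 FPKM, lmo2 at 71.3 FPKM, meis1 at 53.8 FPKM, hlfa at 47.4 FPKM, cmyb at 40.1 FPKM and runx1 at 5.25 FPKM. Their median was 15.4 FPKM (66.8th rank percentile, 95% interval 46.5 to 86.6), above 95.7% of random lists and 90.01% of random lists of genes with descriptive symbols. Without the genes shared with other lists it lay at the 53.8th rank percentile, above 59.9% of random lists. The erythroid list had a median of 10.1 FPKM (60.2nd rank percentile, 95% interval 35.4 to 71.9), above 83.6% of random lists. The embryonic globin genes hbae3 and hbae1 stood at 252 and 200.01 FPKM, and the division of reads between such similar copies is uncertain. They were followed by hbbe1.1 at 28.5 FPKM and the heme breakdown gene blvrb at 24.3 FPKM. The macrophage list had a median of 2.19 FPKM (35.1st rank percentile, 95% interval 26.2 to 46.1), above 7.24% of random lists and 2.46% of random lists of genes with descriptive symbols, and no member reached 100 FPKM. Among genes of at least 1 FPKM, a scale that lowers the genes kept, its median lay at the 23.1st rank percentile. The list was then above 1.64% of random lists limited in the same way. Its highest members were fcer1gl, lcp1, apoeb and coro1a at 23.5, 19.3, 15.0 and 14.9 FPKM, and the macrophage gene mpeg1 stood at 1.43 FPKM. The neutrophil list had a median of 3.88 FPKM (42.6th rank percentile, 95% interval 30.2 to 75.4), above 27.7% of random lists and 14.77% of random lists of genes with descriptive symbols. With members and random lists both limited to genes of at least 1 FPKM, the neutrophil list lay above 4.75%. Its proteoglycan gene srgn stood at 151 FPKM, the granule genes lyz and mpx at 33.4 and 21.4 FPKM and nccrp1 at 25.6 FPKM. The lymphoid and thrombocyte list had a median of 7.13 FPKM and a median rank percentile of 45.8 (95% interval 13.3 to 83.2). These are separate means over its middle members, ccr9a at 13.4 FPKM (66.0th rank percentile) and il7r at 0.887 FPKM (25.6th). A value of 7.13 FPKM itself lies above the median of all genes, 5.98 FPKM. By its median FPKM the list lay above 58.3% of random lists. This placing was not stable. Without itga2b, which is also in the stem and progenitor list, the median lay at the 25.6th rank percentile, above 2.99% of random lists. With members and random lists limited to genes of at least 1 FPKM, the list kept 7 members and lay above 92.3% of these. Its highest members were the thrombocyte genes itga2b, mpl, gp1bb and f13a1b at 43.2, 42.4, 33.6 and 29.3 FPKM, whereas the lymphocyte genes lck and rag1 stood at 0.339 and 0.0704 FPKM. The highest of its lymphoid members was ccr9a at 13.4 FPKM.

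Markers of most other tissues lay far below the endothelial markers. The pan-endothelial median was 49.9-fold that of the neuronal list, 31.6-fold that of skeletal muscle and 33.9-fold that of mural cells. Among the lists of other tissues set against it, the ratio was smallest for mesenchyme and cartilage, 10.6-fold, and it was 16.7-fold for the erythroid list. Neuronal genes had a median of 3.37 FPKM (40.5th rank percentile, 95% interval 35.7 to 55.6), above 15.45% of random lists and 5.25% of random lists of genes with descriptive symbols. With members and random lists both limited to genes above 0, they lay above 4.51%. The highest were stmn2a, vamp2, neurod and tubb5 at 24.0, 17.5, 17.1 and 16.7 FPKM. Glial and neural progenitor genes had a median of 1.33 FPKM (29.4th rank percentile, 95% interval 24.2 to 37.7), above 3.64% of random lists. Their highest member, the Notch receptor gene notch1a at 181 FPKM, is also in the list of vascular signalling genes, and mdka, slc1a2b and fabp7a followed at 43.7, 7.77 and 7.04 FPKM. Retina and lens genes had a median of 5.12 FPKM (47.2nd rank percentile, 95% interval 27.9 to 60.3), above 38.8% of random lists. The cone opsin genes opn1lw2, opn1sw2 and opn1mw1 stood at 63.2, 40.03 and 26.2 FPKM and the photoreceptor factor gene crx at 15.8 FPKM. Skeletal muscle genes had a median of 5.33 FPKM (48.0th rank percentile, 95% interval 31.2 to 58.5), above 40.7% of random lists. The parvalbumin genes pvalb1 and pvalb2 stood at 61.6 and 27.8 FPKM and the myosin light chain genes mylpfa and mylz3 at 30.4 and 27.6 FPKM. Mural genes had a median of 4.95 FPKM (46.6th rank percentile, 95% interval 24.5 to 73.3), above 38.9% of random lists. The highest were foxc1b, the smooth muscle myosin gene myh11a, rgs5a and notch3 at 32.2, 19.2, 11.7 and 11.4 FPKM, and pdgfrb stood at 5.39 FPKM. Liver, pancreas and gut genes had a median of 1.80 FPKM (33.1st rank percentile, 95% interval 27.3 to 38.3), above 1.88% of random lists. With its 9 members listed at 0 left out, and random lists drawn from genes above 0, the median was 2.55 FPKM, above 0.63% of random lists. The carboxypeptidase gene cpb1 was highest at 55.3 FPKM, before apoa2, tfa and f10 at 38.3, 25.7 and 15.9 FPKM. Pigment cell genes had a median of 0.756 FPKM (24.3rd rank percentile, 95% interval 14.5 to 32.8), above 1.39% of random lists. None of 14 reached 10 FPKM, and the highest were gch2, pmela, pmelb and ltk at 2.72, 2.25, 1.76 and 1.08 FPKM. Cardiac muscle genes had a median of 0.347 FPKM (18.7th rank percentile, 95% interval 13.8 to 62.6), above 0.41% of random lists. Only 5 of its 13 members exceeded 1 FPKM, and among genes of at least 1 FPKM their median lay at the 48.9th rank percentile. The cardiac list held tnnc1a, a troponin gene, at 185 FPKM and the factor gene gata4 at 144 FPKM. The members gata5 and tnni1b stood at 11.3 and 8.49 FPKM, whereas the cardiac myosin genes myl7 and vmhc stood at 0.641 and 0.347 FPKM. Ranking among genes of at least 1 FPKM lowers the genes kept. The medians of the neuronal, glial, liver, pancreas and gut and pigment lists then lay at rank percentiles of 26.3, 12.8, 15.0 and 10.2. Against random lists limited in the same way, these lists lay above 0.67%, 0.04%, 0% and 0.71%.

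The epidermis list and the mesenchyme and cartilage list differed in how many members were abundant. In the epidermis list 7 of 22 members exceeded 10 FPKM and 2 exceeded 100 FPKM, and in the mesenchyme and cartilage list 17 of 24 and 6 did. In the epidermis list the keratin genes krt8 and krt18 stood at 1494 and 370.3 FPKM, ranks 31 and 200, while icn, krt5 and krt4 stood at 85.6, 59.06 and 39.7 FPKM and the epithelial adhesion gene epcam at 6.24 FPKM. The list's median was 4.81 FPKM (45.8th rank percentile, 95% interval 25.2 to 83.6), above 34.0% of random lists. In the mesenchyme and cartilage list the collagen gene col2a1a stood at 1817 FPKM, rank 25, 7.65-fold above the next member, col11a1a at 237 FPKM. Without col2a1a, 16 of the other 23 members exceeded 10 FPKM. The matrix genes sparc, postnb and col1a1a stood at 178, 124 and 105.6 FPKM, ucmab at 116 FPKM and the cartilage matrix gene matn1 at 50.1 FPKM. This list had a median of 15.8 FPKM (69.2nd rank percentile, 95% interval 51.1 to 92.1), above 97.8% of random lists and 94.95% of random lists of genes with descriptive symbols. With members and random lists both limited to genes above 0 it lay above 93.9%.

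**Figure D2:**
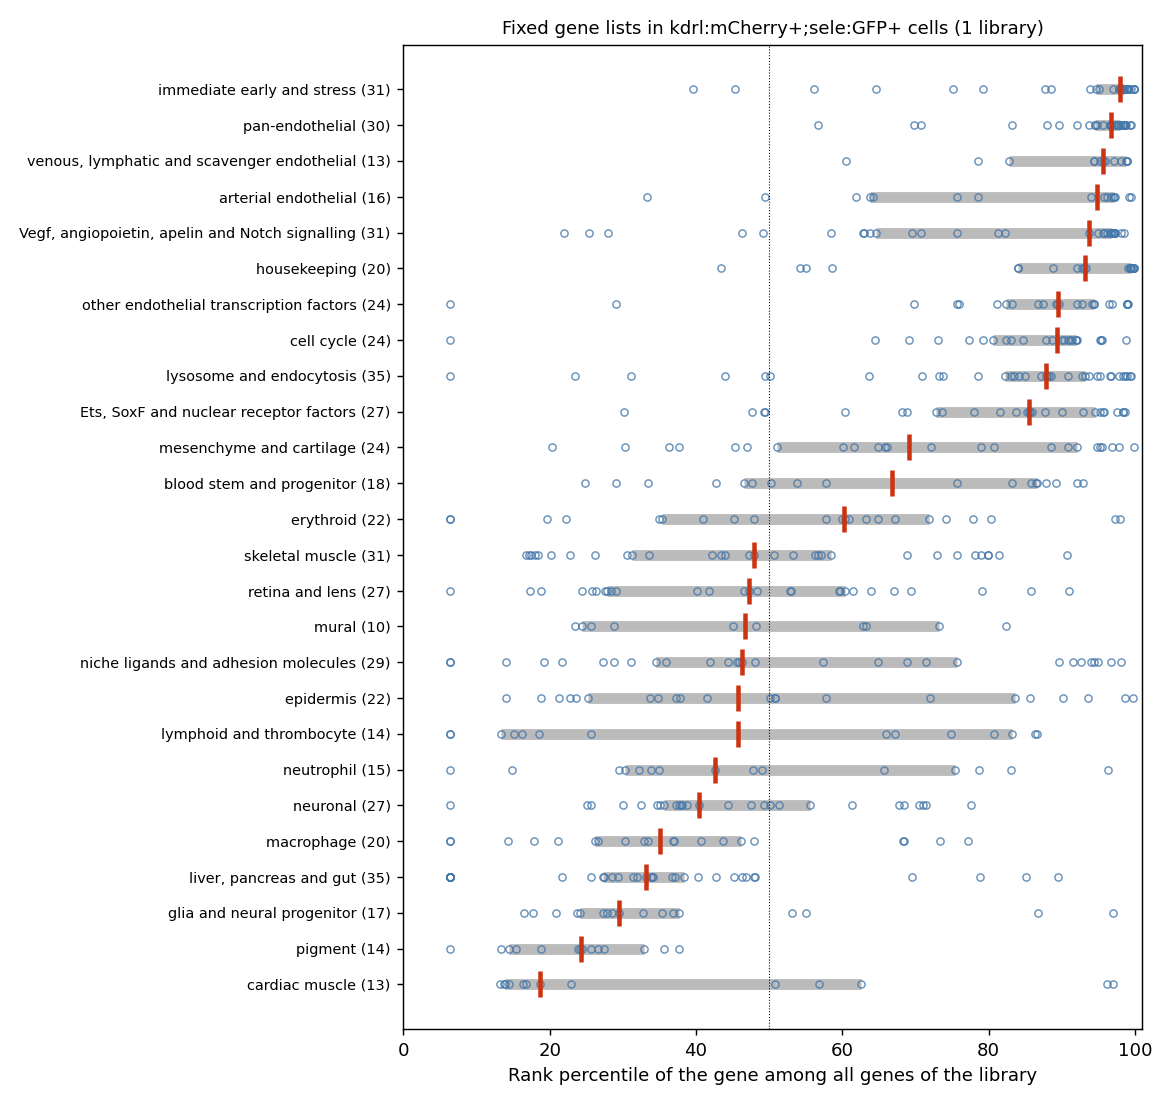
Rank percentile within the library of double positive cells (0 lowest, 100 highest) of each gene of the 26 fixed lists; circles are genes, red ticks are list medians, grey bars are 95% order-statistic intervals of the median over members, and numbers in parentheses are members in the table. The medians of the 3 endothelial lists lie at 96.8, 95.7 and 94.9, and those of the pigment and cardiac muscle lists at 24.3 and 18.7.

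Cell division and stress genes were both abundant. Of 24 cell cycle genes in the table, 23 exceeded 10 FPKM. The replication clamp gene pcna stood at 401 FPKM, the histone gene h2afx at 123 FPKM, the ubiquitin-conjugating enzyme gene ube2c at 120.0 FPKM, the mitotic kinase gene cdk1 at 114 FPKM and mki67 at 71.9 FPKM. Their median of 54.3 FPKM lay at the 89.3rd rank percentile (95% interval 80.6 to 91.9), above all 10000 random lists. Immediate early and stress genes had the highest median of the 26 lists, 252 FPKM, at the 98.0th rank percentile (95% interval 94.7 to 98.5) and above all random lists. The transcription factor genes jun and fos stood at 2573 and 2315 FPKM, the small heat shock gene hspb1 at 1841 FPKM, and btg2 and egr1 at 849.5 and 424 FPKM. These genes are known to respond to tissue dissociation, and every cell of this library was dissociated and sorted. Housekeeping genes had a median of 81.3 FPKM (93.2nd rank percentile, 95% interval 84.0 to 99.4), above all random lists. The elongation factor gene eef1a1l1 stood at 2713 FPKM, the ribosomal protein genes rplp0 and rps18 at 2065 and 1272 FPKM, ppiab at 1239 FPKM and the actin genes actb2 and actb1 at 795 and 646 FPKM.

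The most abundant single entry was the noncoding RNA gene rn7sk at 53182 FPKM, which took 9.95% of the summed FPKM of the table, and the RNase P RNA gene rpph1 followed at rank 3 with 5403 FPKM. The 80 ribosomal protein genes took 15.8% of the summed FPKM with a median of 713 FPKM. Among the remaining genes the highest were the chaperone gene dnajb1b at 3241 FPKM, the ubiquitin gene ubb at 3157 FPKM and tpt1 at 2829 FPKM. They were followed by eef1a1l1, jun, fos, LOC795545 at 1916 FPKM, hspb1 and col2a1a. The chromatin genes hist2h3c and hmgn2 stood at 1693 and 1484 FPKM, LOC100500728 at 1457 FPKM, the translation factor genes eif5a and eif5a2 at 1447 and 1361 FPKM, the thymosin gene tmsb4x at 1304 FPKM and the apoptosis gene pmaip1 at 1240.4 FPKM.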

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

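The alternatives that use descriptive symbols, synonyms, unshared members or genes above 0, and the random lists limited by level, were chosen after the data were seen. With 1 library analysed, no replicate could be left out, and summing rows per symbol changed nothing because no symbol occurred more than once. Ranking among the genes in both tables was not run, since the table of the kdrl:GFP cells was not used. Ranks among genes above a level are on another scale, on which every gene kept has a lower percentile unless it is the highest, so they do not measure stability. Among genes of at least 1 FPKM, 21 of 26 list medians were lower and 5 higher, with differences of -18.1 to 30.2. The medians were 23.1 for macrophage, 28.7 for neutrophil, 26.3 for neuronal, 12.8 for glia and neural progenitor, 15.0 for liver, pancreas and gut and 10.2 for pigment. Those of the cardiac muscle list (48.9) and the lymphoid and thrombocyte list (73.8) were higher, since many of their members lie under 1 FPKM and were left out. Among genes above 0 the medians were 34.1 for neuronal, 19.2 for glia and neural progenitor, 6.87 for cardiac muscle and 13.5 for pigment. With members and random lists both limited to genes above 0, which takes out the members listed at 0, 10 lists lay above 95% of random lists and 6 below 95% of them, compared with 12 and 4 for all genes. The same numbers were found with genes of at least 1 FPKM, where the cardiac muscle list lay above 48.1% of random lists with 5 members. The blood stem and progenitor list lay above 89.6% and 93.1%, and the mesenchyme and cartilage list above 93.9% and 88.3%, in these settings. Among genes with descriptive symbols, all 26 medians were lower, with differences of -5.80 to -0.289 rank percentiles, and 3 left their 95% interval over members: neuronal (34.8), glia and neural progenitor (23.7) and cardiac muscle (13.1). Against random lists of descriptive symbols, 10 lists lay above 95% of the random lists, compared with 12 against all genes, and 5 lay below 95% of them, compared with 4, as the macrophage list went from above 7.24% to above 2.46%. The blood stem and progenitor list then lay above 90.01% and the mesenchyme and cartilage list above 94.95% of them. Synonyms supplied members to 10 lists and moved none out of its interval. The largest move was that of the arterial list, to 83.7. Leaving out members shared between lists moved none of 15 lists out of its interval, but it lowered the Vegf, angiopoietin, apelin and Notch list to 67.1, the arterial list to 77.1 and the lymphoid and thrombocyte list to 25.6, above 2.99% of random lists. The intervals come from the spread of the same members, and some are wide. Staying inside them, here or with synonyms, therefore does not show that a median is stable. As a share of the summed FPKM, kdrl took 0.0801% and sele 0.0777%, with ranks unchanged by construction. The unknown depth limits all statements on genes near 0.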

Other observations

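All families, divisions of lists and tests in this part were chosen after the values were seen. Several gene families showed 1 or a few dominant members. Among 29 claudin genes, the median was 1.09 FPKM, and cldn5b at 653 FPKM was followed by cldn11a at 99.5 FPKM and cldnj at 60.2 FPKM. Among 15 integrin subunit genes, itgb1b stood at 494 FPKM and itga5 at 90.6 FPKM. Of the 10 laminin and nidogen genes, lamb1a, nid1b and lamc1 were highest at 199, 144 and 95.3 FPKM. All 8 Smad genes exceeded 10 FPKM, with smad5 at 103 FPKM, and the Bmp receptor gene acvrl1 stood at 80.4 FPKM and the Bmp family gene bmp16 at 102 FPKM. The endothelin receptor gene ednraa stood at 368 FPKM and the ligand gene edn2 at 135 FPKM. The secreted binding protein genes igfbp7 and igfbp1a stood at 573 and 293 FPKM. Members found through synonyms included vsg1, now plvapb, a gene of endothelial diaphragms, at 835 FPKM, and myct1 at 477 FPKM.

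Hox genes mark position along the body axis, and the median over all genes of the library was 5.98 FPKM. The 26 genes of groups 1 to 8 had a median of 3.39 FPKM with hoxb6a highest at 25.1 FPKM. The 5 genes of group 9 had a median of 10.2 FPKM with hoxb9a at 26.8 FPKM. The 17 genes of groups 10 to 13 had a median of 0.960 FPKM, and the highest, hoxd11a, stood at 2.51 FPKM. No library of another body region was analysed, so no position is inferred.

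The high ranks of the 3 endothelial lists may reflect that well-studied genes carry descriptive symbols and rank higher than provisional ones, whatever the cell type. Descriptive symbols did rank higher, with a median of 7.75 FPKM over 11737 symbols against 0.944 FPKM over the other 2844. Ranked among descriptive symbols only, the medians of the pan-endothelial, the venous, lymphatic and scavenger and the arterial list were 96.3, 95.05 and 94.1. Each of the 3 lists still had a median above those of all 10000 random lists drawn from descriptive symbols alone. A descriptive symbol by itself therefore does not account for these ranks. The pool held most genes of the library and was not limited to well-studied ones. It cannot decide whether being well studied raised the ranks. The comparison with cells that lack the reporters stays open.

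The high rank of immediate early and stress genes may be a response of the cells to dissociation and sorting or a property of the cells in the embryo. Their list also lay above all 10000 random lists of descriptive symbols, so a descriptive symbol by itself does not account for the rank. How well studied these genes are was not tested. The median of the list lay at the 98.0th rank percentile. Dissociation and sorting and a state in the embryo cannot be told apart here, because every cell of the only library analysed was dissociated and sorted.

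The 6 thrombocyte members of their list had a median of 31.5 FPKM and all exceeded 10 FPKM, against a median of 0.185 FPKM for the 8 lymphoid members, of which ccr9a was highest at 13.4 FPKM. Without krt8 and krt18 the epidermis list had a median of 3.19 FPKM and a maximum of 85.6 FPKM. Without col2a1a the mesenchyme and cartilage list had a median of 13.5 FPKM.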
